A study of Homo sapiens with 6 samples.

How the data were processed

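RNA from MCF-7 cells, transfected for 48 h with siControl or siUSP36, was extracted with Trizol and made into BGISEQ-500 libraries, 3 per group. The deposited values were FPKM per gene (fragments per kilobase of transcript, scaled to the mapped fragments of the library) computed by the authors and rounded to 2 decimals, per the file headers. The aligner, the genome build and the annotation behind them are not given in the sources used here. The headers name the knockdown libraries after DUB1, a listed synonym of USP36, where the labels say siUSP36, and the grouping followed the labels. Read counts were not used here, so the depth of each library is unknown and no counting interval was computed.

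The values of 18597 genes were read as deposited, of which 591 were at 0 in every library. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested (11406 genes, 61.3%). Values were transformed to log2(FPKM + 1), which shrinks the fold changes of genes at low levels. Differences between siUSP36 and siControl were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A log2 fold change of at least 1 in size counted as 2-fold. The level of USP36 was also compared with a two-sided exact permutation test, computed in R. Similarity between libraries was measured by Pearson correlation and principal components of the tested genes, and libraries of a group differed in at least 99.3% of gene values, so none was deposited in duplicate.

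Before the data were examined, 38 gene lists, the tests, the main settings and the rule for naming genes were fixed. Lists with at least 5 tested members (32 of the 38) were compared with the other genes by camera at a preset correlation of 0.01, adjusted over the lists. Camera with a correlation estimated from the libraries called 0 lists, also where the estimate lay below the preset. This form takes its degrees of freedom from the 6 libraries, the preset form from the number of genes. The estimated form therefore has less power here. Fry, which asks whether the members of a list move on balance in one direction and does not compare them with other genes, called 21. Members passing were counted over all tested genes and adjusted over the list alone. Named genes were USP36, ESR1, MYC and TP53, then the 8 largest rises and 8 largest falls among genes that passed, whose groups did not overlap and whose higher mean was at least 5 FPKM, and up to 3 members per list with the smallest p among those that passed, or the member with the smallest p where none did. Some lists were defined by the start of the gene symbol, which takes in members outside the class named, such as H1-0 among the histones and USP6NL among the deubiquitinases. Lists of targets also hold parts of the pathway itself, such as TEAD1 among the YAP/TEAD targets and TGFB1 and TGFB2 among the TGF-beta targets.

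Transcript sequences came from GENCODE release 29, with a reference transcript for 11301 tested genes (99.1%). Sequence motifs of 7 bases were ranked over 11029 genes with a 3' UTR of at least 50 bases (96.7%). The ranking score was the mean shift of the fold change of genes that hold the motif, corrected for GC content and length. It was multiplied by the square root of the number of those genes and divided by the SD over all genes. The ranking was repeated in a random part of the 11029 genes, where the same motifs led, and both were tested in the remaining 5515 genes. Over all 11029 genes they were compared with rearrangements of their own bases and with the site lengthened to 8 bases. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 (rank correlations with GC content) and matplotlib 3.10.9 were used for these steps and the figures.

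The limma model was tested on simulated data with the same 11406 genes. It recovered 42% of 100 genes changed by a log2 fold of 0.3 and 98% of 100 genes changed by a log2 fold of 1, with 7 unchanged genes called. With no gene changed it made 0 calls. A list of 30 genes shifted by 0.3 was called, and 0 of 20 lists with no shift were. The simulated noise was independent between genes and the lists were random, so false calls of lists whose members move together were not tested. The simulation also changed far fewer genes (200) than passed in the data, so its recovery need not hold for them.

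Alternatives tried were median-ratio scaling, quantile normalization, no filter on low values, a mean of at least 5 FPKM, pseudocounts of 0.1 and 0.5, no intensity trend, robust variance, a term for the replicate number, stricter thresholds, the other set tests and leaving out each library in turn. Chosen after seeing the data were a correction of each library for transcript GC content and length (natural splines with 5 degrees of freedom each), the exclusion of genes whose 3' UTR holds the hexamer AGAGAT or CGGAGA or was not searched, and both together. The results were also recomputed for all 10 splits of the 6 libraries into 3 against 3.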

Results

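Gene expression was measured by RNA sequencing in MCF-7 cells, an established human breast cancer cell line that carries the estrogen receptor. The cells had been transfected for 48 h either with a control small interfering RNA (siControl) or with one directed against USP36 (siUSP36), a ubiquitin-specific protease of the nucleolus. Each group held 3 libraries, and the comparison asked what a lower level of USP36 does to the transcriptome of these estrogen receptor-positive cells. The deposited values were FPKM for 18597 genes per library, which summed to between 556564 and 582242 FPKM. Between 11297 and 11356 genes reached 1 FPKM in a library. Read counts were not among the values used, so the depth of each library is unknown and no counting error can be given. Pearson correlations of log2 values over the tested genes ran from 0.996 to 0.998 between libraries of one group and from 0.980 to 0.985 between groups. The first principal component held 79.3% of the variance and separated the groups. The labels do not state that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

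USP36 itself was lower in each siUSP36 library than in any siControl library. The siControl libraries held 15.6, 16.9 and 19.1 FPKM of USP36, with a mean of 17.2 ± 1.79 (SD, n = 3). The siUSP36 libraries held 7.27, 6.04 and 7.78 FPKM, with a mean of 7.03 ± 0.894 (SD, n = 3), which left 40.8% of the control level. The log2 fold change was −1.18 with a standard error of 0.09 (limma, adjusted p = 1.42e-07). A two-sided exact permutation test of the 6 values gave p = 0.1, the smallest value that 3 against 3 libraries allow.

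**Figure D1:**
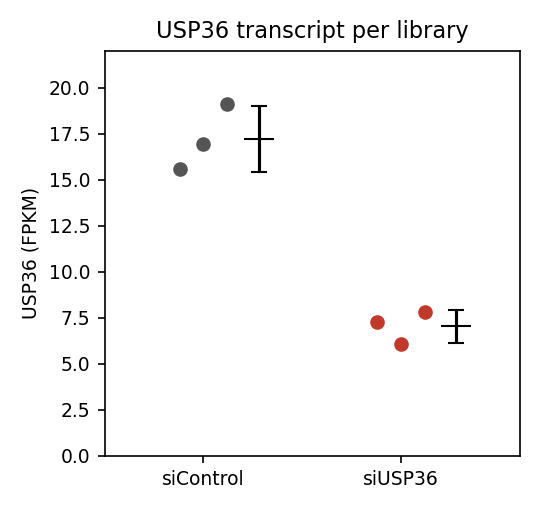
USP36 level in FPKM (vertical axis) in each of the 3 siControl and 3 siUSP36 libraries (points), with the group mean and SD beside them (bars). The siControl libraries lie at 15.6 FPKM or above and the siUSP36 libraries at 7.78 FPKM or below.

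Knockdown went with many small changes and few large ones. The genes that fell most were SMYD2, a lysine methyltransferase, from 12.9 ± 0.582 to 2.43 ± 0.14 FPKM, and TMEM30B, a subunit of phospholipid flippases, from 23.0 ± 1.56 to 4.99 ± 1.08 FPKM (SD, n = 3 each). Next came the phospholipid phosphatase PLPP2, from 60.4 to 15.7 FPKM, the phosphatase regulator PPP1R11, from 73.0 to 21.9 FPKM, and the mismatch repair gene MSH2, from 11.8 to 2.96 FPKM. TMEM14B fell from 79.3 to 26.1 FPKM, PRR11 from 18.2 to 5.48 FPKM and the tight junction gene CLDN1 from 26.2 to 8.22 FPKM. Among the genes that rose, the amino acid transporter SLC7A8 went from 5.68 to 18.0 FPKM, the tropomyosin TPM4 from 103 to 294 FPKM and the opioid growth factor receptor OGFR from 25.1 to 71.6 FPKM. SNCG, which encodes gamma-synuclein, rose from 2.95 to 8.89 FPKM, and RGS19, a regulator of G protein signalling, from 14.7 to 38.5 FPKM. SERHL2 rose from 30.2 to 81.1 FPKM. The log2 fold changes of these falling genes lay between −2.02 and −1.56 and those of the rising genes between 1.33 and 1.51, and each kept its 3 libraries per group apart.

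The largest fold changes upward are less certain. SLX1B was listed at 0.46, 0.68 and 10.1 FPKM in the siControl libraries and at 44.2, 36.4 and 44.7 FPKM in the siUSP36 libraries (log2 fold change 3.82 ± 0.51 SE), but it has a near-identical copy, SLX1A, with which reads may have been shared. ZASP was listed at 1.46, 0 and 1.81 FPKM in the siControl libraries and at 7.89, 16.8 and 10.9 FPKM in the siUSP36 libraries.

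**Figure D2:**
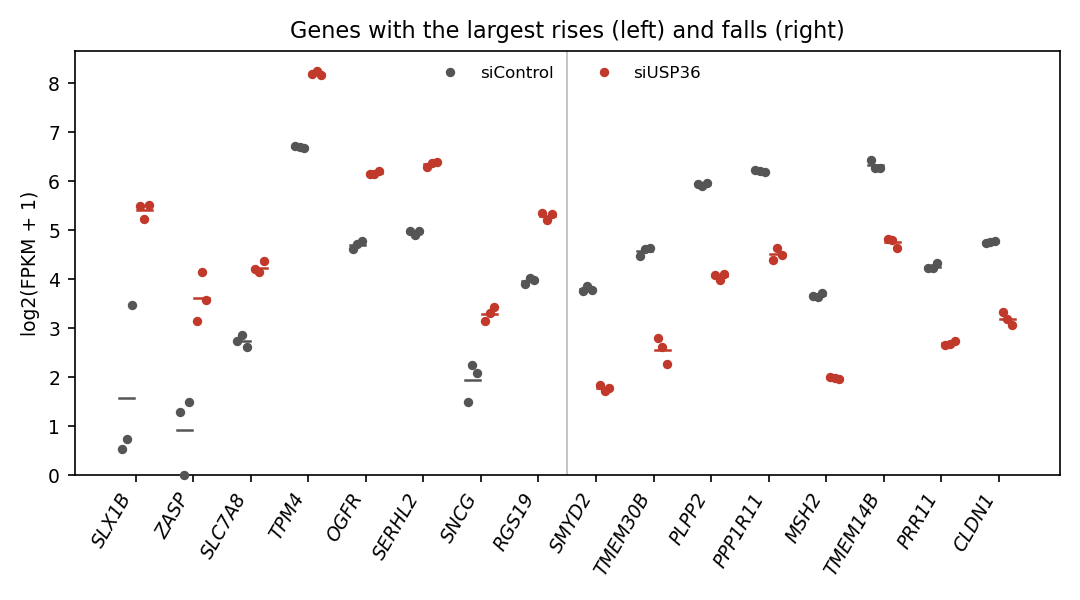
Expression as log2(FPKM + 1) (vertical axis) of the 8 genes with the largest rises and the 8 with the largest falls, by the rule fixed in advance. Points are the 3 siControl and 3 siUSP36 libraries and short lines are group means; in each gene the groups do not overlap, and SLX1B and ZASP show the widest spread among control libraries.

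In all, 5893 of the 11406 tested genes (51.7%) passed an adjusted p of 0.05 in limma, 2674 higher and 3219 lower after the knockdown. Of these, 157 changed at least 2-fold, 49 upward and 108 downward. The balance of rises and falls depended on the setting, with 2970 higher and 2942 lower under quantile normalization and 2979 and 2954 after a correction of each library for transcript GC content and length. Among 6808 genes without a seed site, meaning a searched 3' UTR with neither AGAGAT nor CGGAGA, 1826 were higher and 1424 lower. At 2-fold, 33 were higher and 21 lower. With the correction added, 1609 of these genes were higher and 1759 lower, and at 2-fold 17 and 15. That exclusion and the correction were chosen after seeing the data. A pseudocount of 0.1 gave 116 higher and 202 lower genes at 2-fold. The median absolute log2 fold change of the genes that passed was 0.32, and the median over all tested genes was −0.03. The groups did not overlap in 6675 genes (58.5%), against 10% by chance. ESR1, which encodes the estrogen receptor alpha, fell from 47.8 ± 2.07 to 37.2 ± 3.35 FPKM (SD, n = 3), a log2 fold change of −0.35 (adjusted p = 2.88e-04). The proto-oncogene MYC fell from 106 ± 2.42 to 85.2 ± 4.88 FPKM, a log2 fold change of −0.31 (adjusted p = 1.00e-04). TP53, the gene of the tumour suppressor p53, stood at 73.2 ± 1.6 and 73.1 ± 1.08 FPKM (adjusted p = 0.990).

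These changes went with properties of the transcripts. Across the 11029 tested genes with a 3' UTR in the reference, the fold change rose with the GC content of the transcript (Spearman's rho 0.478 across genes, which are not independent replicates). In the fifth of genes with the lowest GC content, 118 genes rose and 1066 fell, while in the fifth with the highest, 1106 rose and 170 fell. The 3' UTRs of SMYD2, TMEM30B and PPP1R11 hold the heptamer AAGAGAT, which 52 of 105 genes that fell at least 2-fold carried (49.5%), 564 of 5296 genes that did not pass (10.7%) and 116 of 2584 genes that rose (4.49%). These shares are not adjusted for the 3' UTRs, whose median length was 1851, 1025 and 778 bases in the same order, or for the median GC content of the transcripts (44.1, 49.3 and 58.0%). The heptamer was chosen after the fold changes were seen. Among the genes named by list, PRSS23, RPL7L1, TFRC, BAK1, XIAP, NFKB1, PSMB6, NDUFS1, SDHAF2, GCLM, AJUBA, TGFB2, LYZ and USP28 hold it too. H2BC5, IER2 and PRSS23 of these lists, and TPM4 of the largest rises, hold CGGAGAA, the heptamer that ranked first for upward shifts.

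Genes that estrogen induces were lower after the knockdown. Of the 40 tested members of that list, 27 fell, 5 rose and 8 did not pass, and adjusted over the list alone 28 fell and 7 rose. The median log2 fold change was −0.29. SIAH2, a ubiquitin ligase, fell from 69.6 to 43.1 FPKM and the protease gene PRSS23 from 29.1 to 14.9 FPKM, while IGFBP4, which binds insulin-like growth factors, rose from 20.3 to 35.9 FPKM. The classical targets GREB1 and TFF1, named after their values were seen, fell from 13.5 to 9.02 FPKM and from 724 to 573 FPKM. The other members that rose, also named after their values were seen, were ADCY9, MAPT, RAB31 and CTSD. The list passed camera at the preset correlation of 0.01 (adjusted p = 6.24e-04), but not with the correlation estimated from these libraries (adjusted p = 0.265 with an estimated correlation, the highest of its 20 alternatives, of which the lowest gave 3.54e-05).

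Genes of the cell cycle were lower as well. In the list of G2/M and mitosis, 30 of 39 tested members fell, none rose and 9 did not pass, and 31 fell when adjusted over the list alone. The kinesin KIF11 fell from 10.8 to 7.04 FPKM, the kinesin KIF4A from 6.53 to 3.95 FPKM and the mitotic kinase AURKA from 69.5 to 52.9 FPKM. Of 40 tested genes of G1/S and DNA replication, 23 fell, 16 did not pass and 1, the cyclin CCNE1 (named after its value was seen), rose, with the same counts of passing genes adjusted over the list alone. The replicative helicase genes MCM6 and MCM7 fell from 21.2 to 13.2 FPKM and from 177 to 129 FPKM, and the flap endonuclease FEN1 from 32.7 to 23.1 FPKM. The median log2 fold change was −0.22 in both lists, with camera adjusted p = 2.51e-05 for G2/M and mitosis and 8.80e-04 for G1/S and DNA replication. Neither held with the correlation estimated from these libraries (adjusted p = 0.365 with an estimated correlation in both, the highest of 20 alternatives, of which the lowest gave 1.11e-08 for G2/M and 1.46e-05 for G1/S). The correction for transcript GC content and length left 17 mitotic genes lower and 2 higher, with a median log2 fold change of −0.10.

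Genes of ribosome production in the nucleolus, where the USP36 protein resides, went down in larger number than up. Of 43 tested members, 23 fell, 2 rose and 18 did not pass, and 24 fell and 2 rose adjusted over the list alone. NCL, which encodes nucleolin, fell from 137 ± 3.39 to 69.9 ± 5.55 FPKM (SD, n = 3). The 2 that rose were NOLC1, a nucleolar chaperone of small nucleolar ribonucleoproteins, from 28.2 to 57.4 FPKM, and TCOF1, a factor of ribosomal RNA transcription, from 18.6 to 27.7 FPKM. The median log2 fold change was −0.14 (camera adjusted p = 0.00783; adjusted p = 0.241 with an estimated correlation, and from 7.61e-05 to 0.241 over its 20 alternatives). Of 15 tested genes of the RNA polymerase I machinery, 5 fell and 1 rose, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.479). Its median of −0.05 turned to 0.01 under quantile normalization. Its examples were TTF1, from 6.41 to 4.55 FPKM, and TAF1C, from 25.0 to 21.3 FPKM. The cytosolic ribosomal protein list was not called either (13 lower and 6 higher of 80, and 11 and 3 adjusted over the list alone; adjusted p = 0.605). Its counts depended on the scaling, with 28 lower and 12 higher under quantile normalization, which called the list, and 18 and 12 after the correction for GC content and length.

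Genes of the integrated stress response and targets of the YAP and TEAD regulators were also lower. In the list of the integrated stress response, 15 of 23 tested genes fell, 2 rose and 6 did not pass, with the same counts adjusted over the list alone. CHAC1, which degrades glutathione, fell from 75.8 to 44.6 FPKM, the asparagine synthetase ASNS from 335 to 239 FPKM and STC2 from 56.7 to 39.2 FPKM. DDIT4 and SESN2, both inhibitors of mTOR signalling and named after their values were seen, rose with log2 fold changes of 0.38 and 0.25. The median of the list was −0.25 (camera adjusted p = 0.00694; adjusted p = 0.241 with an estimated correlation, and from 2.94e-05 to 0.241 over its 20 alternatives). Of 10 tested YAP/TEAD targets, 8 fell, 1 did not pass and 1, NUAK2 (named after its value was seen), rose, with the same counts of passing genes adjusted over the list alone. AMOTL2 fell from 14.1 to 7.88 FPKM, AJUBA from 13.9 to 7.86 FPKM and TEAD1 from 3.01 to 1.44 FPKM. Its median was −0.50 (camera adjusted p = 0.0129; adjusted p = 0.495 with an estimated correlation, and from 0.00322 to 0.495 over its 17 alternatives).

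Interferon response genes had the highest median change of the 32 lists given a set test. Of 34 tested members, 26 rose, 2 fell and 6 did not pass, with the same counts of passing genes adjusted over the list alone. OAS1, an activator of antiviral RNA decay, rose from 20.9 ± 0.554 to 41.0 ± 0.465 FPKM, its relative OASL from 3.88 ± 0.158 to 9.52 ± 0.146 FPKM, and the ubiquitin-like modifier ISG15 from 93.2 ± 7.12 to 173 ± 3.51 FPKM (SD, n = 3 each). The 2 that fell, named after their values were seen, were USP18, the protease that removes ISG15 from proteins, from 12.9 to 8.78 FPKM, and HERC6. STAT1, named likewise, did not pass (log2 fold change 0.06). The median log2 fold change was 0.49 (camera adjusted p = 2.27e-08; adjusted p = 0.0661 with an estimated correlation, and from 7.84e-10 to 0.0661 over its 20 alternatives).

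Genes of the p53 response, histone genes and genes of fatty acid synthesis showed smaller upward shifts. Among 30 tested p53 targets, 13 rose, 6 fell and 11 did not pass, and 14 rose and 6 fell adjusted over the list alone. BTG2, an antiproliferative gene, rose from 91.2 to 187 FPKM, FDXR from 25.9 to 40.2 FPKM and GDF15 from 916 to 1213 FPKM, while MDM2, named after its value was seen, had a log2 fold change of −0.05 and did not pass. The median was 0.09, but 0.16 after the correction for GC content and length (15 higher, 5 lower) and 0.31 in the 18 members without a seed site (11 higher, 3 lower). With both together it was 0.17 (10 higher, 4 lower). The list passed narrowly (camera adjusted p = 0.0369; adjusted p = 0.528 with an estimated correlation, and from 0.00365 to 0.528 over its 20 alternatives). The call was lost without siControl replicate 1 (adjusted p = 0.0591), without siUSP36 replicate 1 (adjusted p = 0.062) and with genes of at least 5 FPKM on average (adjusted p = 0.0507).

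In the histone list, 15 of 34 tested genes rose, 3 fell and 16 did not pass, and 16 rose and 3 fell adjusted over the list alone. H2BC5 rose from 19.8 to 50.7 FPKM, H2AC8 from 5.37 to 9.12 FPKM and H2BC4 from 3.68 to 6.95 FPKM, while H2AC11, H2BC15 and H2AC6, named after their values were seen, fell. The list also took in H1-0, which is not tied to replication, and H4C14 and H4C15 had equal values, so that their reads cannot be told apart. Its median was 0.15 (camera adjusted p = 0.0261; adjusted p = 0.495 with an estimated correlation, and from 0.00824 to 0.495 over its 20 alternatives). The call was lost without siControl replicate 2 (adjusted p = 0.0551), after the correction for GC content and length (adjusted p = 0.409) and without genes with a seed site (adjusted p = 0.233). The median was 0.10 after the correction (11 higher, 6 lower) and 0.19 in the 18 members without a seed site (9 higher, 2 lower), so that the latter call was lost on fewer members with no smaller median.

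Of 14 tested genes of fatty acid synthesis, 6 rose, 1 fell (the desaturase SCD, named after its value was seen) and 7 did not pass, with the same counts of passing genes adjusted over the list alone. SREBF1, a regulator of lipid synthesis, rose from 136 to 176 FPKM, FADS2 from 10.6 to 15.4 FPKM and ELOVL1 from 89.2 to 109 FPKM. Its median was 0.14 (camera adjusted p = 0.049; adjusted p = 0.601 with an estimated correlation, and from 0.0108 to 0.601 over its 20 alternatives). The call was lost without siControl replicate 1 (adjusted p = 0.101), siControl replicate 2 (0.0551), siUSP36 replicate 1 (0.0741) or siUSP36 replicate 3 (0.0832), under quantile normalization (0.0929) and without genes with a seed site (0.0578). The median was not smaller in these last settings, at 0.16 under quantile normalization and 0.15 in the 7 members without a seed site (3 higher, 0 lower).

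**Figure D3:**
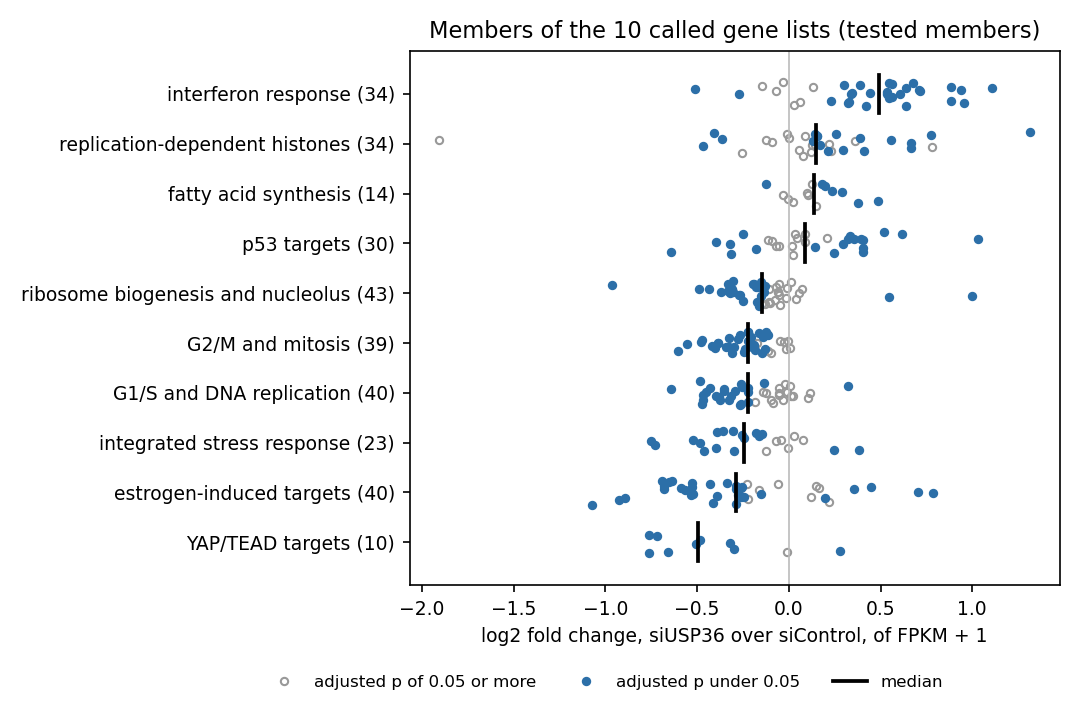
Log2 fold change of FPKM + 1, siUSP36 over siControl (horizontal axis), of each tested member (points) of the 10 called gene lists (rows, with the number of tested members); filled points passed an adjusted p of 0.05 and black bars are medians. The interferon response list has the highest median, 0.49, and the YAP/TEAD list the lowest, −0.50.

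Other lists held large changes of single genes without a call for the list. Among genes of the luminal cell type, 7 of 16 fell and 4 rose, with the same counts adjusted over the list alone (adjusted p = 0.724). The keratin KRT18 fell from 4963 to 3924 FPKM and XBP1 from 1419 to 1101 FPKM, while the transcription factor SPDEF rose from 202 to 306 FPKM. Of 34 MYC targets outside the nucleolus, 14 fell and 5 rose, with the same counts adjusted over the list alone (adjusted p = 0.288). The transferrin receptor TFRC fell from 53.9 to 22.1 FPKM and SHMT2 from 198 to 162 FPKM, and EIF4A1 rose from 465 to 583 FPKM. Among 45 tested genes whose symbols start with USP, 18 fell and 6 rose, with the same counts adjusted over the list alone (adjusted p = 0.0891). After the correction for GC content and length, 11 of these were lower and 10 higher, and their median went from −0.13 to 0.00. Besides USP36, the deubiquitinases USP12 and USP28 fell from 10.8 to 4.03 FPKM and from 4.94 to 2.16 FPKM. In the antioxidant list, 6 of 23 fell and 6 rose, with the same counts adjusted over the list alone (adjusted p = 0.934). Thioredoxin reductase TXNRD1 fell from 216 to 93.2 FPKM and the ferritin heavy chain FTH1 from 4303 to 2292 FPKM. That list had a median of 0.02 and a mean of −0.09, and its median turned negative under quantile normalization (6 higher, 8 lower).

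Cell death, adhesion and growth factor genes moved both ways. Of 19 pro-apoptotic genes, 8 rose and 4 fell (adjusted p = 0.288), with CASP7 up from 7.45 to 19.4 FPKM and BAK1 down from 27.2 to 14 FPKM. Of 11 anti-apoptotic genes, 4 rose and 4 fell (adjusted p = 0.896), with BCL2L1 up from 61.8 to 84.4 FPKM and XIAP down from 9.12 to 5.85 FPKM. Among 23 genes of epithelial junctions, 10 rose and 7 fell, and 10 and 8 adjusted over the list alone (adjusted p = 0.383). CLDN3 rose from 146 to 217 FPKM while CLDN1 fell. Its median of −0.01 had the opposite sign to its mean of 0.01 and to its test, and it turned positive under median-ratio scaling. Of 17 TGF-beta targets, 8 rose and 5 fell, and 9 and 5 adjusted over the list alone (adjusted p = 0.384), but 7 were higher and 7 lower after the correction for GC content and length. TGFB1 rose from 23.8 to 54.5 FPKM and ID3 from 53.8 to 105 FPKM, whereas TGFB2 fell from 8.39 to 2.40 FPKM. Both apoptosis lists kept their counts when adjusted over the list alone.

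The lists of protein production, folding and turnover outside the nucleolus were not called at the preset correlation. Of 80 cytosolic ribosomal protein genes, RPL36AL fell from 239.8 to 166 FPKM and RPL26L1 rose from 56.8 to 74.8 FPKM. Of 78 mitochondrial ribosomal protein genes, 21 fell and 9 rose, and 20 and 8 adjusted over the list alone (adjusted p = 0.470), but 25 were lower and 20 higher after the correction for GC content and length. MRPL58 fell from 45.2 to 17.7 FPKM, while MRPS34 rose from 117 to 171 FPKM and MRPL4 from 183 to 227 FPKM. Of 37 proteasome subunits, 11 fell and 4 rose, with the same counts adjusted over the list alone (adjusted p = 0.601), but 6 were lower and 9 higher after the correction for GC content and length. PSMB6 went down from 174.9 to 120.1 FPKM and PSMC3 went up from 87.4 to 121 FPKM. Of 20 ER chaperones, 5 fell and 3 rose, and 4 and 3 adjusted over the list alone (adjusted p = 0.930), with CRELD2 up from 31.3 to 54.2 FPKM. That list turned with the setting, with 3 lower and 5 higher under median-ratio scaling and 5 and 7 after the correction for GC content and length. Its median of −0.01 became 0.01 under median-ratio scaling, 0.01 under quantile normalization and 0.08 after the correction. Of 16 cytosolic heat shock genes, 5 rose and 4 fell, and 6 and 4 adjusted over the list alone (adjusted p = 0.479), with the HSP90 activator AHSA1 up from 121 to 153 FPKM.

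Of 24 genes of cholesterol synthesis, 8 rose and 5 fell, and 8 and 6 adjusted over the list alone (adjusted p = 0.288), with the decarboxylase MVD up from 55.5 to 85.9 FPKM. Of 93 nuclear genes of oxidative phosphorylation, 17 fell and 7 rose, and 15 and 5 adjusted over the list alone (adjusted p = 0.601). Quantile normalization gave 27 lower and 5 higher and called the list, and the correction for GC content and length gave 22 and 18. The complex I subunit NDUFS1 fell from 27.1 to 18.9 FPKM. Of 32 genes of glycolysis and hypoxia, 12 rose and 8 fell, with the same counts adjusted over the list alone (adjusted p = 0.197), and the phosphofructokinase PFKL rose from 45.0 to 80.1 FPKM. Of 30 genes of autophagy and the lysosome, 10 rose and 7 fell, with the same counts adjusted over the list alone (adjusted p = 0.509), and the median of 0.03 turned to −0.01 after the same correction. Within it, BECN1 fell from 37.0 to 20.4 FPKM and ATG5 from 12.4 to 6.0 FPKM. Of 8 metallothioneins and AhR targets, 4 rose and 2 fell, and 5 and 2 adjusted over the list alone (adjusted p = 0.322), with MT1F up from 37.2 to 57.1 FPKM.

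Among 19 immediate early genes, 8 rose and 4 fell, with the same counts adjusted over the list alone (adjusted p = 0.196), and IER3 rose from 81.4 to 147 FPKM. The median of 0.11 became 0.01 after the correction for GC content and length. Without siControl replicate 3 that list was called (adjusted p = 0.0392, within a range from 0.0147 to 0.698 over its 20 alternatives). Of 13 NF-kB and cytokine genes, 4 rose and 3 fell, with the same counts adjusted over the list alone (adjusted p = 0.601), and NFKB1 fell from 11.6 to 7.18 FPKM. Of 5 mesenchymal genes, 2 rose and 3 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.288), and the integrin ITGA5 rose from 8.84 to 13.7 FPKM.

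Lists with fewer than 5 tested members were not tested as sets. None of 3 snoRNA host genes passed, and no mitochondrially encoded gene was listed. The basal markers ACTA2 and KRT17 rose from 21.7 to 37.6 FPKM and from 1.62 to 3.21 FPKM, and the fibroblast marker COL1A1 rose from 4.36 to 6.10 FPKM. Of the immune markers, LYZ fell from 1.25 to 0.84 FPKM and CD68 rose from 1.70 to 2.32 FPKM, while of the endothelial markers ENG rose from 0.67 to 1.43 FPKM and EMCN fell from 2.67 to 1.95 FPKM. The calls of single markers were not firm: CD68 did not pass without siControl replicate 1 (adjusted p = 0.141) or siUSP36 replicate 1 (0.131), LYZ did not pass without siUSP36 replicate 1 (0.0539) or siUSP36 replicate 2 (0.06), and KRT17 did not pass without the filter on low values (0.0642). Most of these markers lay at low levels, and fold changes of log2(FPKM + 1) understate changes of such genes.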

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

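The correction for GC content and length and the exclusion of genes with a seed site were chosen after seeing the data. USP36 stayed lower and past its threshold in all 18 alternatives, with log2 fold changes from −1.28 (pseudocount 0.1) to −1.09 (without siUSP36 replicate 2). Of the results for named genes, 1993 kept their direction and side of the threshold, 11 fell short of it, 1 passed newly and 0 reversed. Of those for lists, 593 kept theirs, 25 fell short, 15 passed newly and 1 reversed. The number of genes changed was 5629 with a block for the replicate number, 5902 with median-ratio scaling (2890 higher, 3012 lower), 5912 with quantile normalization (2970 higher, 2942 lower) and from 4970 to 5848 with 1 library left out. It was 157 at 2-fold, 3250 without genes with a seed site (1826 higher, 1424 lower) and 3368 (1609 higher, 1759 lower) with that exclusion and the GC and length correction together; the last pair tested fewer genes (6808). After the correction alone 5933 genes passed (2979 higher, 2954 lower), of which 4097 were shared with the 5893, 4089 in the same direction.

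With an estimated correlation 0 lists were called. That held also for ribosome biogenesis, the integrated stress response and interferon response, whose estimated correlations (−0.019, −0.025 and −0.007) lay below the preset 0.01. For these lists a higher correlation among members does not account for the loss. The estimated form also has fewer degrees of freedom, which come from the 6 libraries, so lost calls can reflect low power. The adjusted p was 0.265 for estrogen-induced targets, 0.241 for ribosome biogenesis, 0.241 for the integrated stress response, 0.365 for G1/S, 0.365 for G2/M, 0.495 for YAP/TEAD targets, 0.495 for histones, 0.528 for p53 targets, 0.601 for fatty acid synthesis and 0.0661 for interferon response. Fry, which does not compare a list with other genes, called 21 lists, among them MYC targets (0.0106), pro-apoptotic genes (0.048), heat shock proteins (0.00485), cholesterol biosynthesis (0.00575), autophagy (0.0395), glycolysis (0.00179), immediate early genes (0.0147), TGF-beta targets (0.00485), mesenchymal genes (0.0173) and USP-family genes (0.0173). It put antioxidant and NRF2 targets down (0.0467), the reverse of camera. Quantile normalization added cytosolic ribosomal proteins (0.0466), MYC targets (0.0116) and oxidative phosphorylation (0.0129) and lost fatty acid synthesis (0.0929). A mean of at least 5 FPKM lost p53 targets (0.0507) and fatty acid synthesis (0.0758). The GC and length correction lost histones (0.409). Leaving out genes with a seed site lost histones (0.233) and fatty acid synthesis (0.0578) on fewer members (18 of 34 and 7 of 14). Their medians there were 0.19 and 0.15, no smaller than the 0.15 and 0.14 of all members. The correction and the exclusion together lost both lists as well (0.243 each), with a median of 0.15 for histones and a smaller one, 0.10, for fatty acid synthesis. That setting added mitochondrial ribosomal proteins (0.0333). With each library left out in turn, adjusted p ran from 0.00824 to 0.0551 for histones (lost without siControl replicate 2), from 0.0141 to 0.101 for fatty acid synthesis (lost without siControl replicates 1 and 2 and siUSP36 replicates 1 and 3), from 0.0229 to 0.062 for p53 targets (lost without replicate 1 of either group) and from 0.0392 to 0.310 for immediate early genes (called without siControl replicate 3). YAP/TEAD targets had under 5 members with a mean of at least 5 FPKM or without genes with a seed site, so no value was obtained there. The cause was not tested for the other changes. Depth is unknown, so its limit on genes at low levels cannot be given.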

Other observations

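The motifs AAGAGAT and CGGAGAA were picked from these data, and their tests in held-out genes were chosen after the result was seen, as were the GC and length correction and the exclusion of genes with a seed site. Of the 10 splits of the 6 libraries into 3 against 3, the real one included, 1 gave at least 5893 changed genes, namely the real one (at most 1 gene in any other), and 4, again with the real one, gave at least 10 called lists (at most 11 in another). With 10 splits the share cannot go under 0.1. The interferon list was called in all 9 other splits (lowest camera adjusted p 3.40e-04). Each of these splits keeps a pair of libraries of one group together on each side, so part of the group difference remains in it. Ribosome biogenesis, p53 targets, histones and fatty acid synthesis had a lower camera adjusted p in another split than in the real one. Their lowest there were 0.00222, 0.00957, 5.75e-04 and 3.31e-04, against 0.00783, 0.0369, 0.0261 and 0.049. The calls of these lists were thus no stronger than those of mixed splits. The remaining called lists had their lowest adjusted p in the real split, but each was also called in other splits. Besides interferon, G2/M and mitosis was called in 8 of the 9 and G1/S and DNA replication in 5. Estrogen-induced targets were called in 4, the integrated stress response in 2 and YAP/TEAD targets in 1.

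Genes with AAGAGAT in the 3' UTR shifted downward on average after the knockdown and genes with CGGAGAA upward. Of those with AAGAGAT, 791 were lower, SMYD2, TMEM30B and PPP1R11 among them, 564 did not pass and 116 were higher. Of those with CGGAGAA, 98 were higher, TPM4 and H2BC5 among them, 98 did not pass and 36 were lower, PRSS23 among them. In the 5515 genes held out of a ranking repeated in the rest, which the same motifs led, the mean shifts were −0.11 and 0.18 (730 and 129 genes). Permutation of the genes gave p = 0.001 for each, the smallest that 1000 permutations can give, which argues against a pick by chance. Over all genes, those used to pick them included, the motifs lay −8.43 and 6.95 SDs from the mean of their own rearrangements. Their ranking scores were −16.0 and 8.28, against means of −0.69 and 0.37 for the rearrangements. Since the motifs were picked as the most extreme, this comparison cannot exclude base composition. The shift was −0.17 with the 8-base site AAGAGATA (373 genes, 95% interval −0.21 to −0.13) and −0.00 with AGAGAT alone, a grading consistent with seed pairing of a small RNA in the knockdown libraries. As a hypothesis, part of the falls may therefore be off-target effects of the transfected RNA and not effects of lower USP36. The labels give no siRNA sequences, so neither motif can be matched to one. AAGAGAT occurs in the coding sequence of USP36, but that transcript holds 27.2% of all heptamers, so this decides nothing. For CGGAGAA the shift was 0.22 with the 8-base site TCGGAGAA (60 genes), 0.14 with CGGAGAA outside that site (172 genes) and 0.03 with CGGAGA alone. The 95% intervals with and without the 8-base site, 0.11 to 0.32 and 0.09 to 0.19, overlap, so a step between them is not established. With CGGAGAA only in the coding sequence the shift was 0.07 (1090 genes), against 0.14 with it only in the 3' UTR (205 genes). For AAGAGAT these shifts were −0.03 (1226 genes) and −0.10 (1147 genes). By the same hypothesis, part of the rises may be off-target effects of a small RNA in the siControl libraries, which stays untested.

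Fold changes rose with the GC content of the transcript, from a median of −0.19 in genes of the lowest GC content (2207 genes) to 0.16 in those of the highest (2206 genes). Across 6808 genes with neither hexamer the rank correlation was 0.470, which argues against seed pairing at AGAGAT or CGGAGA as its source. Pairing at other sites was not tested. A difference in library preparation between the groups cannot be told apart from an effect of the knockdown, because any such difference would coincide with the groups. Libraries of the siUSP36 group also differed by GC content among themselves (largest rank correlation 0.575, replicate 3 against replicate 1), so a GC trend arose between libraries with the same label. Per 10 percentage points of GC, the log2 slope was at most 0.09 in size within siUSP36 and 0.02 within siControl, and from 0.11 to 0.22 between groups. A biological effect of USP36 on GC-rich transcripts stays open and untested.

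Interferon response genes, such as OAS1, ISG15 and OASL, were higher after the knockdown. Their median log2 change was 0.45 after the GC and length correction and 0.54 without genes with a seed site, against 0.49 without either. Thus neither GC content and length nor a site in a member's own 3' UTR accounts for the rise as a whole. The exclusion cannot test seed pairing in other genes that act on these members. RNA of immune cells in the knockdown libraries is unlikely as a source, since the highest level of PTPRC, LYZ, CD14 or TYROBP there was 0.99 FPKM, for LYZ, which was lower than in the siControl libraries (1.03 to 1.41 FPKM). The median member rose by 1.93 FPKM, whereas the immune marker CD68 stood at 1.70 FPKM in siControl and 2.32 FPKM in siUSP36 (adjusted p = 0.0303, but 0.141, the highest of its alternatives, without siControl replicate 1 and 0.131 without siUSP36 replicate 1; the lowest was 0.0175, under quantile normalization). A response to the transfected RNA itself stays open beside an effect of lower USP36, since the labels name no second siRNA, and neither was tested.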
